A study of Mus musculus with 6 samples.

How the data were processed

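RNA precipitated with phosphorylated ribosomes was measured in the ventral bed nucleus of the stria terminalis (vBNST) of mice. Per the labels, ribosomes were precipitated with an antibody against phosphorylated S6, a protein of the small ribosomal subunit, the RNA was depleted of rRNA, and stranded libraries were prepared. There were 6 libraries, 3 labelled Con and 3 labelled CS, taken 90 min after a CS+ or CS- test. The labels do not say whether the CS libraries come from the CS+ or the CS- test, nor what the Con animals received, so the groups are named here as the labels name them. They also do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The antibody catalogue number in the labels rises by the same step from each sample to the next, so the labels do not settle which antibody, or whether more than 1, was used. No batch or date is given.

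The deposited table gives RPKM (reads per kilobase of gene length and per 1e6 assigned reads) for 29547 rows in 6 columns, with the chromosome, position, strand and length of each row. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and counted with featureCounts of Subread 1.5.1, and the builds named are GRCm38 and mm10. The aligner and the strand setting of the counting are not given in the sources used here. The product of RPKM and length summed to the same total in every column, and with a tolerance of 0.01 read 100% of the values above 0 came out as whole reads, so the reads behind each value were computed from the table. Assigned reads numbered 765769, 1200995 and 1427784 in Con libraries 1, 2 and 3, and 1578775, 1365181 and 2342686 in CS libraries 1, 2 and 3. At this depth 1 read on a row of 1 kilobase equals between 0.427 and 1.31 RPKM. A row without a read in a group can still be present. The floor used for its fold was 3 reads over the group's 3394548 (Con) or 5286642 (CS) reads, which covers the counting error of that group only. Reads of the other group were taken as exact, and library totals were used without median scaling. Folds against the floor therefore are not strict lower bounds and are not on the scale of the other fold changes.

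Rows that overlap in the annotation shared reads. Among rows lying inside another row on the opposite strand, the inner row held more reads than the outer row in 9 of 336 library values, and n-R5s195 and Gm42781, on opposite strands, held the same 159 reads. Counts of called rows therefore are not counts of independent transcripts, and 5S rRNA copies, pseudogenes, microRNAs within host genes and overlapping genes are uncertain. Among genes named below, Apol7d overlaps Fn1, Sp9 Cir1, Ppp1r1b 1700003D09Rik and Gabra4 Gabrb1 on the opposite strand. So do Nefl and Nefm, Ndufa2 and Tmco6, Malat1 and Gm37376, and Lhfpl3 and A930003O13Rik. How many reads these pairs share was not measured.

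Rows with a mean RPKM of at least 0.5 over the 6 libraries were tested (20550 rows). Values were taken as log2(RPKM + 0.1), each library's median deviation from the mean of all libraries was subtracted, and CS was compared with Con by limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Median scaling removed a shift of 0.37 on the log2 scale by which the deposited values of the CS libraries lay higher. Fold changes are on the log2(RPKM + 0.1) scale, and every difference is CS minus Con. The offset draws the change of low rows with reads in every library toward 0. Where libraries hold no read, it largely sets the size of the change instead. Mir22, without a read in Con, had a log2 fold change of 7.87 on this scale and was 3.21-fold higher against the floor. Levels are given as RPKM after median scaling.

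There were 36 gene lists fixed before the data were examined, covering activity-regulated genes, neuronal and non-neuronal cell type markers, receptors, channels, synaptic genes, stress responses, ribosomal and mitochondrial genes and noncoding RNAs. Each was tested with limma's camera at a preset correlation of 0.01 over lists with at least 5 tested members, and members were also adjusted over the list alone. The genes named were set by a rule made at the same time. It takes up to 12 higher and 12 lower genes with the largest change among those past the threshold whose CS libraries all lie on one side of the Con libraries, leaving out predicted-gene, clone and pseudogene symbols, and fills open places by the smallest p. It adds the 4 members of each called list and the 2 members of each other list with the smallest p, and Fos, Npas4, Arc, Egr1, Rps6, Crh, Prkcd, Sst, Gad1, Slc17a6 and Malat1. Other genes named were chosen after their values were seen, and are marked so. Gene types come from the RefSeq table of GRCm38.p6, in which 22977 row names matched a symbol and 778 more a synonym; 84.2% of the tested rows had a type.

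Shares of reads or of summed RPKM were compared by an exact two-sided permutation test, in which 3 libraries against 3 cannot give a p below 0.1. The alternatives tried were other pseudocounts, filters, scalings and variance models, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were limma voom on the recovered reads for the 10463 rows with at least 60 reads, with and without the replicate block, voom with library totals in place of median scaling, the same 60-read filter with the log2 RPKM model, protein-coding genes only, and shares of reads.

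The models were tested on simulated reads drawn from the libraries' own means and totals, with 200 genes changed by 2- or 4-fold between CS and Con. Over 20244 rows the log2 RPKM model called 0 of 96 genes changed 2-fold and 20 of 93 changed 4-fold, and it also called 35 unchanged rows, all 35 of them without a read in one group. Over 10396 rows with at least 60 reads, voom called 20 of 57 genes changed 2-fold, 46 of 51 changed 4-fold and 1 unchanged row. The simulation held no difference in scaling between the groups, so it does not cover the dependence of the counts on the scaling. All rows were drawn with the same dispersion, the spread beyond counting error. Its value, 0.032, was the median over rows with at least 200 reads, so no row was more variable than another. The numbers of unchanged rows called therefore are not error rates for the real calls. Calls on rows without a read in one group are given with their reads.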

Results

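The data are RNA profiles of phosphorylated ribosomes from the mouse vBNST, a part of the extended amygdala, in 3 Con and 3 CS libraries. Phosphorylation of S6 rises in active neurons, so precipitation of phosphorylated ribosomes is meant to enrich the RNA that these cells translate. None of the 6 libraries is labelled as input RNA, so this enrichment could not be measured. The nuclear RNA Malat1 held 4.12% of the reads on average. Differences between CS and Con therefore need not lie in translated RNA of active neurons. The study asked which molecules take part in the response of this region to unpredictable threat, and the comparison its design implies is that of CS with Con. Libraries held between 765769 and 2342686 assigned reads, and the lowest Con library had 15407 rows with a read against 18583 in the lowest CS library.

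After median scaling, transcripts lower in CS made up most of the calls on rows with at least 60 reads, 140 lower and 1 higher. On such rows voom, chosen after seeing the data, called 27 higher and 658 lower with median scaling and 272 higher and 253 lower with library totals in its place, so with voom this balance depends on the scaling. The 1 higher in the log2 RPKM model was Atp5c1, which encodes the gamma subunit of the mitochondrial ATP synthase and rose from 14.8 ± 1.58 to 31.6 ± 2.37 RPKM (SD, n = 3 per group; log2 fold change 1.09 ± 0.16 SE, limma adjusted p = 0.0392). The most strongly lower of those with at least 60 reads named by the rule were 5S rRNA copies, led by n-R5s109 (log2 fold change -3.35), n-R5s2 (-2.99) and n-R5s195 (-2.91), followed by Eif3j2, a second copy of the gene for a translation initiation factor subunit (-2.44 ± 0.34 SE), BC085271 (-2.39 ± 0.22), n-R5s118 (-2.29) and Apol7d (-2.24 ± 0.24). Per the labels the RNA was depleted of rRNA, so the 5S reads are those that remained. Whether depletion differed between the libraries was not tested. Anp32b, which encodes an acidic nuclear histone chaperone and was chosen after its values were seen, fell from 578 ± 17.5 to 139 ± 10.7 RPKM (limma adjusted p = 0.00565).

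In all, 199 of 20550 rows were called, 36 higher and 163 lower in CS. The balance of these calls turned to 111 higher and 35 lower without the variance trend (58 of the 199 shared) and to 63 higher and 47 lower without Con library 3. Of all tested rows 10685 had a higher and 9865 a lower estimate. At an unadjusted p under 0.05 there were 774 higher and 1803 lower rows. The groups did not overlap in 22.97% of the rows, where 10% is the average expected for exchangeable libraries. Rows share the effects of their libraries, so a single split can lie far from 10%. The share was not computed for other splits, so no excess is established. With the RPKM values as deposited, before the median scaling, 35 rows were called higher and 30 lower, and with quantile normalization 37 higher and 73 lower. All 199 calls kept their direction in both. Without Con library 1, 2 or 3 the count was 61, 297 or 110, and without CS library 1, 2 or 3 it was 8, 15 or 49. By gene type, 5 protein-coding genes were higher and 91 lower, 7 pseudogenes were higher and 21 lower, and 6 microRNA rows were higher and 1 lower.

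**Figure D1:**
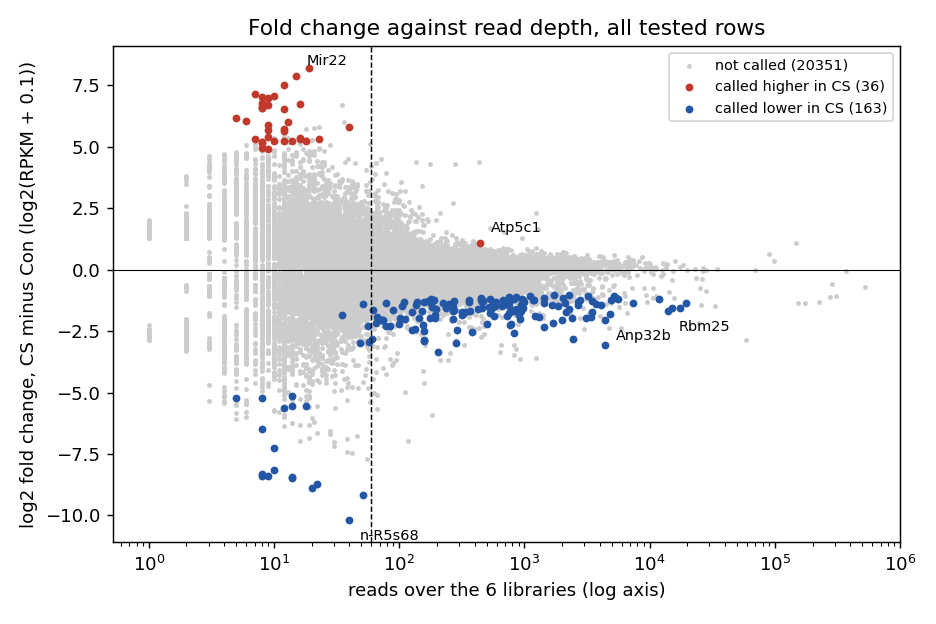
Each point is 1 of the 20550 tested rows, placed by its reads over the 6 libraries (log axis) and its log2 fold change, CS minus Con; red and blue points passed the limma test and the dashed line marks 60 reads. Of the 36 rows called higher, 35 lie left of that line, whereas 140 of the 163 called lower lie right of it.

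The other 35 higher calls all rested on rows without a read in any Con library, and simulated unchanged rows of this kind were also called. The microRNA genes Mir22, Mir432, Mir7047, Mir6537, Mir431 and Mir1966 had 15, 12, 7, 10, 8 and 9 reads over the CS libraries. Against the floor of 3 reads over the group, with the CS reads taken as exact, Mir22 was 3.21-fold and Mir432 2.57-fold higher in CS. Without Con library 3 these folds were 1.86 and 1.49. Mir432 and Mir431 lie within Rtl1 on the opposite strand, and Mir22 lies within its host transcript. Mir6537 and Mir1966 overlap Pou2f2 and Fam65a on the same strand. Bola1, an iron-sulfur cluster assembly factor, had 40 reads in CS and was 8.56-fold higher against the floor (4.96-fold without Con library 3), and the histone gene Hist1h2ad had 9 reads. Cda, Mrps36 and Olfr692 filled the open places with 23, 19 and 19 reads in CS and none in Con, and did not pass the test (limma adjusted p = 0.0555, 0.0573 and 0.0574). In the other direction n-R5s68, Mir3068, n-R5s10, Hist1h4j and Rasl11a, a small GTPase gene, had 40, 14, 10, 12 and 18 reads in Con and none in CS. Against the floor they were 20.8-, 7.27-, 5.19-, 6.23- and 9.34-fold lower in CS. Con library 3 held 32 of the 40 reads of n-R5s68, 8 of the 12 of Hist1h4j and 12 of the 18 of Rasl11a. With 1 library left out the lowest of these folds were 7.17, 4.05, 2.89, 3.47 and 5.20. Of the 21 called genes that the rule takes for their large change, only Mir3068 and n-R5s10 stayed past the threshold without each library in turn. Mir3068 overlaps Gm29362 on the same strand, and each row held 14 reads. With 1 library left out the limma adjusted p of Atp5c1 lay between 0.0671 and 0.172.

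Among the gene lists, transcripts of the nuclear-encoded respiratory chain were higher in CS as a group, while striatal projection neuron markers and abundant small noncoding RNAs were lower. These calls used the preset correlation, and none of the 3 held with a correlation estimated from the data (adjusted p = 0.836, 0.888 and 0.836 in that order). Of 82 respiratory chain genes 63 had a higher and 19 a lower estimate, with a median log2 fold change of 0.26 (camera adjusted p = 0.019, and 0.836 with an estimated correlation). The median was 0.63 as deposited and 0.51 with quantile normalization. The members called when adjusted over the list alone went both ways: Atp5c1 and Ndufa2, a subunit of complex I, were higher, the latter at 22 ± 4.7 RPKM in Con and 47.6 ± 7 in CS, and Atp5k, the ATP synthase subunit e, fell from 217 ± 46.9 to 85.8 ± 2.29 RPKM. Over all genes Atp5c1 and Atp5k passed and Ndufa2 did not (limma adjusted p = 0.0767); Cox7a2l, a respiratory supercomplex factor, had a log2 fold change of -1.05 ± 0.24 SE and did not pass either adjustment by limma, but passed over all genes by voom (limma voom adjusted p = 0.0198).

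Of 15 striatal projection neuron markers, 13 had a lower and 2 a higher estimate in CS, with a median of -0.33 (camera adjusted p = 0.0365, and 0.888 with an estimated correlation). As deposited the median was 0.05, above 0, and the list was not called (camera adjusted p = 0.11). Over the list alone 3 members were lower and over all genes none was, against 5 lower at an unadjusted p under 0.05 with limma and 3 lower by voom. Those called over the list alone were Adcy5, the main adenylyl cyclase of striatal neurons, at 170 ± 17.7 RPKM in Con and 68.8 ± 25.2 in CS, Bcl11b, a transcription factor of these neurons, at 25.8 ± 5.3 and 12.6 ± 3.33, and the retinoid receptor gene Rxrg at 30.7 ± 5.67 and 16.6 ± 3.94. Ppp1r1b, which encodes DARPP-32, had a log2 fold change of -0.79 ± 0.29 SE and did not pass. Of the dopamine and adenosine receptor genes that mark these neurons most narrowly, chosen after their values were seen, Drd1 (-0.33 ± 0.42), Drd2 (-0.61 ± 0.41) and Adora2a (-0.08 ± 0.40) had overlapping groups.

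The abundant small noncoding RNAs had a median of -0.90, with 11 of 14 lower (camera adjusted p = 0.0167, and 0.836 with an estimated correlation). Scarna2, a guide RNA of Cajal bodies, fell from 245 ± 27.2 to 86.2 ± 21.2 RPKM and passed over all genes (limma adjusted p = 0.039). Over the list alone the Y RNA Rny1 (9928 ± 504 RPKM in Con and 3497 ± 95.4 in CS), the minor spliceosomal RNA Rnu12 (log2 fold change -1.08 ± 0.25 SE) and Rny3 (-1.09 ± 0.32) were lower too. The median of the list was -0.53 as deposited and -0.15 with quantile normalization, with which the list was not called (camera adjusted p = 0.38) and Rny3 had -0.20.

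With an estimated correlation 2 lists had an unadjusted p under 0.05. The directional test of fry, which does not compare a list with other genes, called none (9 at an unadjusted p under 0.05). Its mixed test, which takes members changed in either direction, called 21 lists. Leaving out a library ended at least 1 of the 3 calls in each case. The respiratory chain list had a camera adjusted p of 0.0812 without Con library 2, 0.235 without Con library 3 and 0.056, 0.0781 and 0.0707 without CS library 1, 2 and 3. The striatal list had 0.101 and 0.465 without Con library 1 and 2 and 0.0643 and 0.267 without CS library 1 and 3. The small RNA list had 0.085 without Con library 2 and 0.056 and 0.0781 without CS library 1 and 2.

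**Figure D2:**
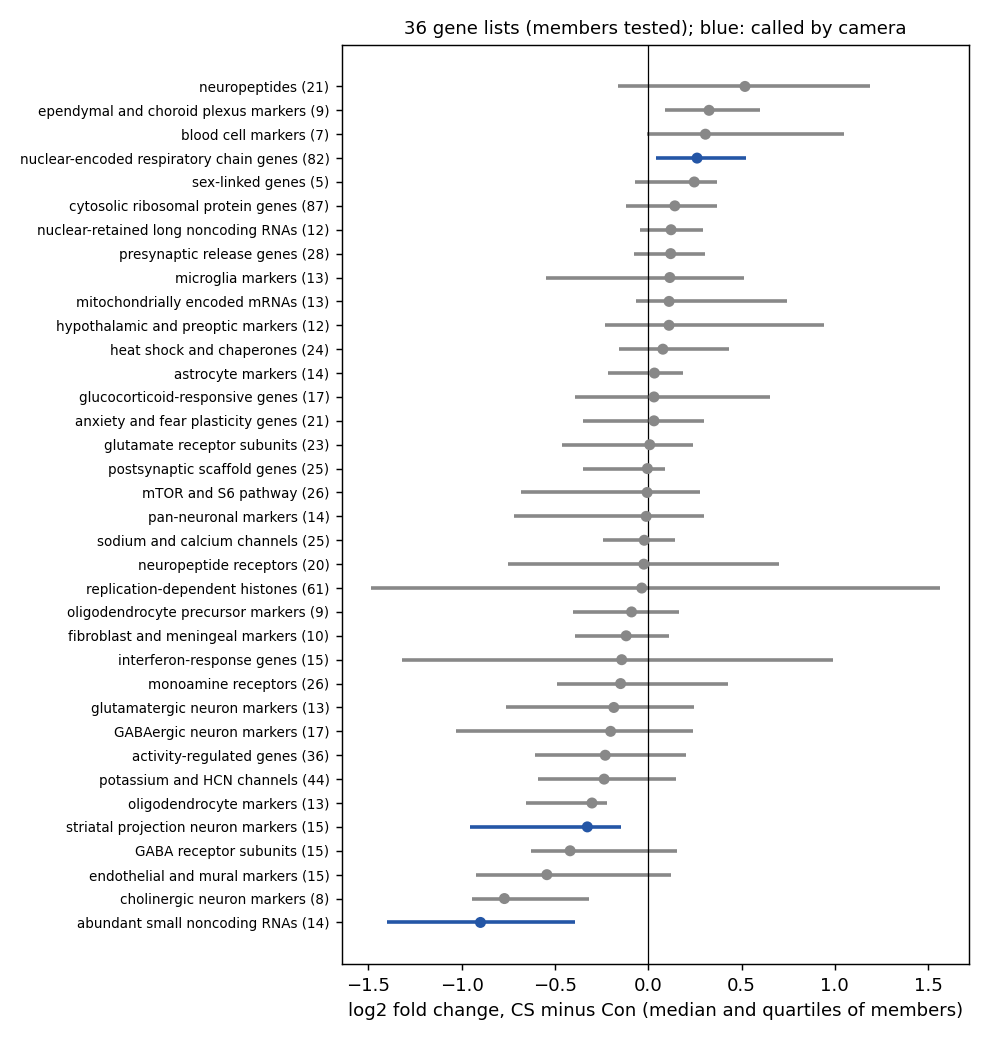
Median (points) and quartiles (lines) of the log2 fold change, CS minus Con, over the tested members of each of the 36 lists, whose number stands in brackets; blue marks the 3 lists called by camera. The small noncoding RNA median lies lowest at -0.90; with the values as deposited, the medians of 16 lists change sign.

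The other 33 lists were not called (camera adjusted p from 0.259 to 0.985). The activity-regulated list joins genes transcribed within minutes of neuronal firing with slower ones. It had 16 members with a higher and 20 with a lower estimate (median -0.23), and as deposited 21 and 15 (median 0.14). Of its 36 members 0 were called over the list alone by limma (2 lower at an unadjusted p under 0.05, 0 by voom). Libraries taken only at 90 min after the test do not show earlier or later changes. Fos had a log2 fold change of -0.37 ± 0.44 SE on 139 reads, Npas4 -0.61 ± 0.63 on 67, Arc 0.40 ± 0.32 on 254 and Egr1 -0.28 ± 0.30 on 156. As deposited, Fos (0.003) and Egr1 (0.10) lay above 0. The phosphatase gene Dusp1 (-1.39 ± 0.42) and Ier5 (-0.76 ± 0.30) had the smallest p of the list. Rps6, which encodes the precipitated S6 protein, had 0.45 ± 0.21 and was not called (limma adjusted p = 0.445).

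GABAergic neuron markers were not called as a list (camera adjusted p = 0.259, median -0.20, and 0.17 as deposited). By limma 6 of 17 members were lower when adjusted over the list alone and 0 over all genes (8 lower and 1 higher at an unadjusted p under 0.05). By voom 6 were lower over all genes, and over the list alone 7 were lower and 1 higher. Those lower over the list alone by limma included the transcription factor genes Sp9 (11.4 ± 1.09 RPKM in Con and 5.54 ± 0.683 in CS), Zfhx3 (9.29 ± 1.36 and 4.97 ± 0.487), Six3 and Lhx6. The genes of GABA synthesis and vesicular loading had estimates above 0, Gad1 0.89 ± 0.32, Gad2 0.17 ± 0.21 and Slc32a1 0.16 ± 0.37, and none was called by limma. Six3, Lhx6, Gad2 and Slc32a1 were chosen after their values were seen. In the glutamatergic list Neurod1 was lower over the list alone (log2 fold change -2.31 ± 0.52 SE, 52 reads), and Slc17a6 had 0.24 ± 0.38.

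Of the neuropeptides only Grp, gastrin-releasing peptide, was called over the list alone, with 8 reads in Con and 0 in CS. Against the floor of 3 reads it was 4.15-fold lower (2.31-fold without CS library 3). Sst, somatostatin, had 240 reads and a log2 fold change of 1.19 ± 0.35 SE with all 3 CS libraries above the Con libraries, and did not pass (limma adjusted p = 0.223). Crh (-0.59 ± 0.55) and the kinase gene Prkcd (-0.35 ± 0.45, and 0.02 as deposited), a marker of a central amygdala and BNST neuron class, rested on 76 and 70 reads. The somatostatin receptor gene Sstr2 was lower over its list alone (log2 fold change -3.08 ± 0.59 SE, 515 reads in Con and 136 in CS). Crhr1 had 16 reads in CS and 0 in Con and was not called. Among channel and synaptic genes, the potassium channel gene Kcnq3 (-1.34 ± 0.23), which carries the M-current, the presynaptic calcium sensor Syt1 (-1.04 ± 0.23) and the neurofilament gene Nefl (-1.01 ± 0.20) were lower over their lists alone by limma, and over all genes none of these 3 by limma and all 3 by voom (limma voom adjusted p = 0.00325, 0.0148 and 0.00879). In the mTOR and S6 pathway list Sesn1, a restraint on that pathway, was lower over the list alone (-1.12 ± 0.19). Among receptor genes that did not pass over their lists by limma, Htr1a had -1.28 ± 0.28 and Gabra4 -1.32 ± 0.41; by voom both passed over all genes (limma voom adjusted p = 0.0137 and 0.0387).

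**Figure D3:**
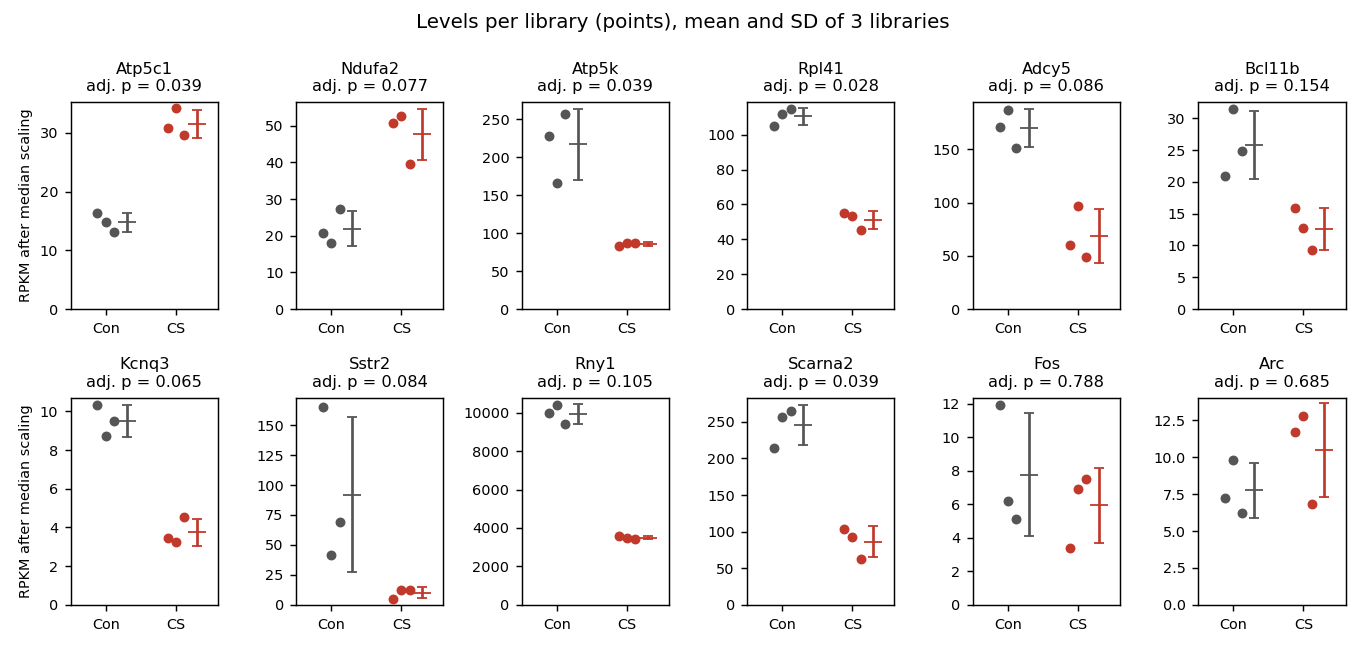
RPKM after median scaling of 12 genes in each Con and CS library (points), with the mean and SD of 3 libraries beside them; titles give the limma adjusted p over all genes. The 3 CS libraries lie above the Con libraries for Atp5c1 and below them for Atp5k, Rpl41 and Scarna2, while the groups overlap for Fos and Arc.

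Markers of other cell types were not called as lists by limma and camera. Oligodendrocyte markers had a median of -0.30, and 0.07 as deposited, with 11 of 13 lower (camera adjusted p = 0.477). By voom the oligodendrocyte and GABAergic lists were called lower at the preset correlation (camera adjusted p = 0.0279 and 0.0191). With an estimated correlation, tested on the log2 RPKM values, both had an adjusted p of 0.888. Over its list alone Lhfpl3, of oligodendrocyte precursors, was lower (-1.79 ± 0.36), as was Foxj1, the ciliogenesis factor of ependymal cells (-1.57 ± 0.36, 61 reads). Lhfpl3, with 117 reads, overlaps A930003O13Rik, with 120 reads, on the opposite strand, so its reads may not be its own. Astrocyte and microglia markers had medians of 0.03 and 0.12 and no member called over the list alone by limma (1 and 2 lower at an unadjusted p under 0.05; by voom none and 1 lower), and Cx3cr1 of microglia had -0.92 ± 0.25. The median of the list and the direction of camera differed in sign for the astrocyte and microglia lists. In the ribosomal protein list Rpl41 fell from 110 ± 4.86 to 51.1 ± 5.25 RPKM (limma adjusted p = 0.0283). The copy Rps3a3 was lower and Rpl36, chosen after its values were seen, higher over the list alone. The median of 87 genes was 0.14 (camera adjusted p = 0.314, and 0.888 with an estimated correlation). At the preset correlation the camera adjusted p was 0.0429 as deposited, 0.00185 with quantile normalization and 0.00691 by voom.

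Over all lists, 34 members were called over the list alone, 5 higher and 29 lower, and 6 of the distinct members tested were called over all genes.

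The make-up of the libraries was compared by shares of summed RPKM and of reads; the share of reads and the rRNA and 7SL classes were chosen after the data were seen. Rows of nuclear and mitochondrial rRNA took 10.8 ± 0.575% of the reads in Con and 7.17 ± 0.123% in CS, and 7SL RNA, the RNA of the signal recognition particle, took 11.5 ± 3.16% and 8.09 ± 1.24% (both exact permutation p = 0.1, the smallest 3 against 3 can give; SD, n = 3). By summed RPKM the same classes took 3.91 ± 0.507% and 3.33 ± 0.347% (exact permutation p = 0.2), and 18.3 ± 1.51% and 17.1 ± 0.922% (exact permutation p = 0.3). The rRNA class counts some reads more than once, because AY036118 and Gm42418 overlap Rn18s-rs5 and share its reads. It also pools both directions. Rn18s-rs5 alone took 3.67% of the reads in Con and 1.90% in CS, whereas the mitochondrial mt-Rnr1 took 0.727% and 1.24% and mt-Rnr2 0.864% and 1.29%. Cytosolic ribosomal protein genes took 0.269 ± 0.0951% of the summed RPKM in Con and 0.498 ± 0.103% in CS, and nuclear-retained long noncoding RNAs 0.294 ± 0.0997% and 0.472 ± 0.147% (both exact permutation p = 0.1). By reads the ribosomal protein genes took 0.757 ± 0.161% and 1.09 ± 0.123% (exact permutation p = 0.1), and the nuclear-retained RNAs 4.55 ± 0.871% and 5.66 ± 1.11% (exact permutation p = 0.4). Small noncoding RNAs (19.3 ± 1.35% and 18.0 ± 0.897%, exact permutation p = 0.2), mitochondrially encoded mRNAs (0.206 ± 0.148% and 0.321 ± 0.135%, exact permutation p = 0.4) and the 10 highest rows (81.2 ± 3.82% and 77.1 ± 2.16%, exact permutation p = 0.2) were shares of summed RPKM too; by reads p was 0.1, 0.5 and 0.1. Malat1, a nuclear long noncoding RNA, alone took 3.68% of the reads in Con and 4.56% in CS, with a log2 fold change of -0.06 ± 0.35 after median scaling and 0.31 as deposited.

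**Figure D4:**
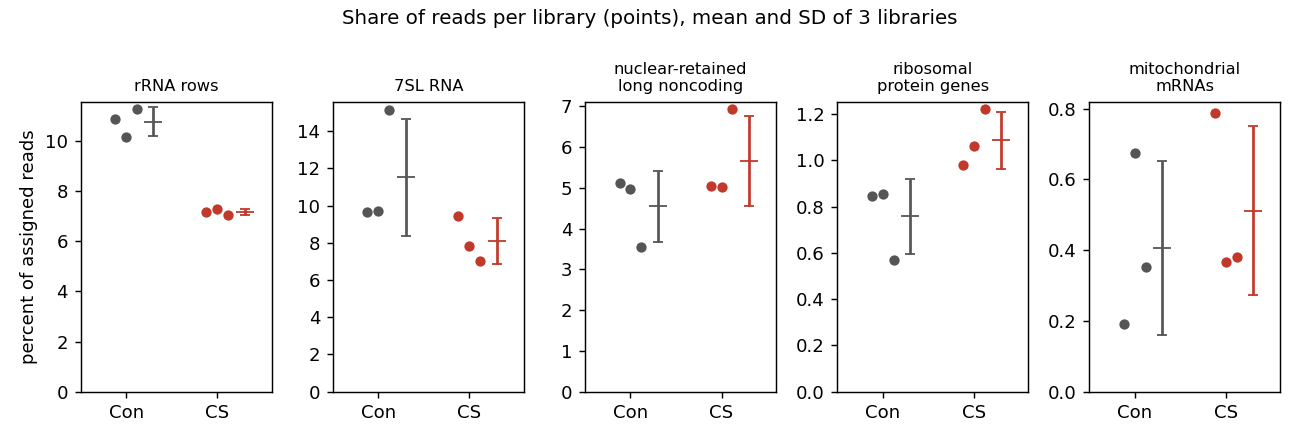
Percent of assigned reads in 5 classes of rows, in each Con and CS library (points), with the mean and SD of 3 libraries. The rRNA rows take between 10.2 and 11.3% in Con and between 7.04 and 7.29% in CS, with reads shared by overlapping rows counted more than once.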

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

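The voom, 60-read and protein-coding settings were chosen after seeing the data. Every row called in the comparison of CS with Con kept its direction in each setting that tested it; causes of the changes below were not tested unless a clause names one. The count of 199 called genes (36 higher, 163 lower) became 112 (87 lower) with a pseudocount of 1, 107 (20 and 87) without a filter, which tests more rows, 65 (30 lower) as deposited, 110 (73 lower) with quantile normalization, 685 (658 lower) by voom, 525 (272 and 253) by voom with library totals and no median scaling, 428 (14 and 414) with at least 60 reads and 1735 at an unadjusted p under 0.05 with at least a doubling or halving. Without the variance trend 111 were higher and 35 lower, and with protein-coding genes only 11 were higher. Leaving out 1 library gave 8 to 297 called genes, 0 to 78 higher and 8 to 219 lower. Lists called, 3, became 6 by voom, 5 with library totals, 0 with an estimated correlation, 0 by the directional test of fry and 0 to 2 without 1 library. The mixed test of fry called 21. List members called over the list alone, 34, became 58 as deposited, 12 without the trend, 55 by voom, 98 with library totals and 5 to 21 without 1 library. The groups share replicate numbers, and the labels do not say that these pair the samples. Same-numbered libraries deviated from their group means with correlations of -0.07, 0.002 and 0.016, and the other pairs with -0.061 to 0.056. At this depth, values so near 0 do not settle whether the samples are paired. With the replicate block limma called 0 genes (0 higher, 0 lower; 1691 at an unadjusted p under 0.05) and 2 list members, and voom with the block called 748 genes (12 higher, 736 lower), 6 lists and 61 members. Direction turned as deposited for Fos (0.0032), Egr1 (0.096), Prkcd (0.021) and Malat1 (0.31), with library totals by voom for the same 4 (0.15, 0.032, 0.043 and 0.31), for Malat1 with a pseudocount of 1 (0.043) and quantile normalization (0.61), and for mt-Nd3 by voom with the block (-0.021); none was called. Without 1 library Fos ranged from -0.62 to 0.0058, Npas4 from -1.04 to 0.031, Slc17a6 from -0.026 to 0.47 and Malat1 from -0.20 to 0.028. The planned quasi-likelihood and negative binomial count models were not run. The quasi-likelihood model was planned for a table of raw counts, and the table holds RPKM. Reads could be computed from it, so count models were possible, and voom on those reads took their place. The planned gene-type filter used the RefSeq table because the table has no type. Depth limits rows under 60 reads, where 58 of the 199 calls lie.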

Other observations

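The tests of sampling and of median scaling, the counts over other splits and the voom model were chosen after the results they bear on were seen. The bounds of the depth, dilution and charged-run tests were set before, but how those 3 tests were read was changed after their values were seen, as given at each.

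By voom, 27 genes were higher in CS. They included Mir770 (962 reads, log2 fold change 1.28, limma voom adjusted p = 0.00852), the chaperone gene Hspa8 (0.63, 0.0225), the glycolytic enzyme gene Eno1 (0.74, 0.034), Sncb, which encodes beta-synuclein (0.65, 0.034), the ubiquitin gene Ubb (0.59, 0.0357), Bex1 (0.65, 0.0271), Ywhaz, a 14-3-3 protein gene (0.67, 0.0442), and Slc25a4, the mitochondrial ADP/ATP carrier (0.61, 0.0429). Of the 658 lower genes, Smpd3, a neutral sphingomyelinase, had -1.77 (0.000308), Rab5a, an early endosome GTPase, -1.96 (0.000329), and the phosphodiesterase gene Pde4a -1.72 (0.000523). These genes were chosen after their values were seen.

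In the comparison of CS with Con more of the called genes were lower than higher, though not in every setting. Without the variance trend 111 were higher and 35 lower, as deposited 35 and 30, and without Con library 3 63 and 47. With every library thinned to 765769 reads, voom still called between 447 and 492 genes lower and 19 to 27 higher over 5 draws, which argues against the smaller depth of the Con libraries as the whole cause. The log2 RPKM model then called 85 to 115 lower and 15 to 30 higher, down from 163 and 36. The bound for this was at least 300 lower genes; a single draw, with 465, was run first, and the lowest of 5 was taken afterwards. With library totals in place of median scaling, voom called 272 genes higher and 253 lower, and 251 of those 253 were also lower with median scaling. The excess of lower over higher genes, which with median scaling was 658 to 27 by voom, therefore may come from the scaling, whereas those 251 lower genes were called both ways. A set of 83 rows, wider than the rRNA and 7SL classes of the report because it also holds 7SK, Rn7s6 and 4 clone rows that overlap the 7SL genes, took 30.9% of reads in Con and 21.5% in CS. Overlapping rows of this set share reads, so these shares count some reads more than once. Without these rows and with no scaling, the median log2 fold change was 0.24 where it had been 0.41, so dilution by these rows may account for part of the shift. The bound set against dilution, a median above 0.2, was met. The median's standard error over libraries, 0.0387, was brought in only after that, and with it the median does not clear the bound, so dilution is left open on a rule added late. Nuclear RNA carried over in Con was also looked at, after its values were seen. The nuclear-retained RNAs had a median of 0.12, with 6 higher and 6 lower, which decides nothing, so this stays open. No biological explanation of the shift was tested.

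Some of the lower genes, chosen after their values were seen and not tested for enrichment, encode proteins with acidic or charged runs: Anp32b (log2 fold change -2.06 ± 0.14 SE), Anp32e (-1.61 ± 0.14), Anp32a (-1.25 ± 0.13), Nap1l1 (-1.30 ± 0.14), Ptma (-1.08 ± 0.14), Ncl (-1.17 ± 0.14), Rbm25 (-1.68 ± 0.13) and Pelp1 (-1.91 ± 0.16). A hypothesis was that reads from purine-rich coding runs were lost in the CS libraries or gained in the Con libraries. The 48 other genes with such runs, listed before their values were seen, had a median of 0.06 (quartiles -0.28 and 0.18), at percentile 73.4 of 10000 lists matched on mean expression, 13 histone chaperones with an acidic run had 0.04, at percentile 56.6, and 9 histone chaperones and partners without a long acidic run had -0.08, at percentile 38.2. None of the 3 lists moved as either explanation would need, and the first and the last met the bound set against it, a percentile above 25. That bound was first read as excluding both explanations. It was wrong, and was set aside after the values were seen, because the lists left out the genes already seen to be lower and so could exclude nothing. What sets these genes apart, including a difference between CS and Con tissue, stays open. Of the 48 genes, 7 were lower when adjusted over that list alone and 1, Zc3h13, over all genes.

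Of the 53 called rows without a read in one group, 35 were higher and 18 lower. The 9 other splits of the 6 libraries gave up to 31 such calls, and no call on a row with reads on both sides, against 146 in the real split. Sampling of few reads may therefore account for a large part of the calls without a read in one group, the 6 microRNA rows among them, but it was not seen to give calls on rows with reads on both sides. The limit for this test was written when the counts of the other splits were known.

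For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with the most called genes (199, highest other 31), lists (3, highest other 2), list members (34, highest other 6) and genes by voom (685, highest other 1). The other splits mix Con and CS libraries, so their counts are not those of libraries without a group difference.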
